A study of Mus musculus with 6 samples.

How the data were processed

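Bulk RNA sequencing was read from 6 libraries of mouse lung endothelial cells in 2 groups of 3. One group was labelled wild type and Cre-negative (WT 1 to 3), the other CSE-KO and Cre-positive (CSE-KO 1 to 3). CSE stands for cystathionine gamma-lyase, which the gene Cth encodes. The Cre driver, the deleted exons, the passage of the cells and whether the replicates were separate animals or separate cultures are not given in the sources used here. Per the labels' protocols, total RNA was purified on Qiagen miRNeasy micro columns with DNase treatment on the column, stranded mRNA libraries were built from 300 ng with a Vazyme VAHTS kit of version 6, and single-end reads of 75 bp were taken on a NextSeq 500. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.3a, Picard 2.21.7, featureCounts 1.6.5 and DESeq2 1.26.0, with genome build mm10. The notes give no role or order for them.

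The deposited table held a whole-number score for each of 18956 genes in each library, which was read as a normalized count, that is a read count divided by a size factor for its library and rounded. No header or label states this unit. It was inferred from the values. Median-ratio size factors recomputed from the table lay between 1.003 and 1.008 in all 6 libraries. Some whole numbers were never used in a library (43 and 128 in WT 1, 70 in CSE-KO 1, and 28, 85, 141 and 197 in CSE-KO 3), and others were filled to excess (16 in WT 2 with 185 genes, between 117 genes at the number before and 86 at the number after). Division followed by rounding leaves such gaps and pile-ups. The factors themselves and the raw counts were not used here, so totals are of normalized counts and only approximate the depth in reads. The smallest row maximum was 3, so genes below it in every library were absent from the table, and no row was mitochondrial. The table held 14266 protein-coding genes, 2027 lncRNAs and 1688 processed pseudogenes. Of its IDs, 18940 were found in GENCODE mouse release 21 (18783 with the same coordinates and 18588 with the same symbol), which gave exonic lengths. Coordinates are on mm10.

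The design fixed before the data were examined called for a count model if the table held raw counts and for limma if it held normalized values. The second case applied, so limma 3.58.1 in R 4.3.3 was used. Values were taken as log2(value + 0.5). Genes with a value of at least 10 in at least 3 libraries were tested with a linear model of group and moderated statistics with a mean trend and robust variances, all two-sided. A gene was called changed at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested), and no further normalization was applied. Fold changes are on the log2(value + 0.5) scale, which understates the change of genes with low values. Changes of genes with many reads per exonic base may be understated too, if reads that share a start position were removed. No fold is given where a group mean was under 3, and values are then given per library or as mean ± SD. P-values measure only the spread between these libraries, which may be technical. The same model was tested on simulated data with 13750 genes drawn from the real means, of which 200 were changed by known folds. At true folds of 1.2, 1.5, 2 and 4, with 50 genes each, 46%, 76%, 88% and 98% were called. Of 13550 unchanged genes, 20 were called, which made up 11.5% of the 174 calls. These shares do not carry over to the data, where 10639 genes were called. The cutoff of the adjustment depends on how many genes change, and the simulated libraries varied by at least counting noise.

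Before the data were examined, 39 gene lists were fixed for pathways, endothelial types and states, other cell types of the lung and sample quality. They overlap in part. Each list with at least 3 tested members was compared with all other tested genes by camera from limma with an inter-gene correlation of 0.01 (two-sided, Benjamini-Hochberg over 37 lists). The count of members changed is given over all genes tested and adjusted over the list alone. The lists were also tested by camera with a correlation estimated for each list and by fry. With an estimated correlation, camera also tests on the few degrees of freedom left by the libraries, far fewer than with a fixed one. Fry tests whether a set moves one way on balance and compares it with no other genes. The rule for named genes, also fixed beforehand, took Cth, the 12 largest rises and 12 largest falls among called genes with a mean of at least 50, groups that did not overlap and a symbol that is not a gene model or pseudogene name, up to 4 members of each list with the smallest adjusted p, and all sex-linked genes. Some genes that the rule selects are not reported here. Other genes named in the text were chosen after their values were seen, as were the 21 gene families of the closing section.

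Alternatives covered recomputed size factors, upper-quartile scaling, filters on low values, the pseudocount, leaving out the 20 most abundant genes, the replicate number as a block, each library left out in turn and a test against a fold of 1.2 with limma treat. Added after the data were seen were equal totals, quantile normalization, a minimum of 50, a correction for reads lost at shared start positions, CSE-KO 2 and 3 counted as 1 sample and WT 1 to 3 counted as 1 sample. Replicate numbers were not used as pairs, because the labels do not say that equal numbers belong together. After the group means were removed, the correlation between libraries of the same number was −0.0008, 0.020 and 0.011. These values could not reveal a pairing, since the WT libraries differed from each other by no more than counting noise. All pairs of replicates were compared with the spread that counting alone would give, as an index that is 1 at counting noise. The 3 WT pairs had indices of 0.750, 0.710 and 0.698 over all genes, and the CSE-KO pairs had 1.64 (1 and 2), 1.93 (1 and 3) and 0.862 (2 and 3). The index of the last pair was 1.11 in genes under 0.01 per exonic base.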

Results

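Gene expression was measured by RNA sequencing in mouse lung endothelial cells, with 3 libraries labelled WT (Cre-negative) and 3 labelled CSE-KO (Cre-positive). The study's title places the comparison in work on cystine import, its oxidative breakdown, histone acetylation and endothelial growth, and the comparison covers how the libraries labelled as knockout of cystathionine gamma-lyase (CSE) differed from those labelled WT. Totals of normalized counts were 6046496, 6028772 and 6052275 in WT 1 to 3 and 5765008, 5698922 and 5760790 in CSE-KO 1 to 3. Between 17744 and 17752 genes were above 0 in the WT libraries and between 18282 and 18357 in the CSE-KO libraries. The median coefficient of variation between replicates was 4.04% in WT and 5.21% in CSE-KO. Values are normalized counts as mean ± SD (n = 3 libraries per group), p-values are from limma, and coordinates are on mm10. Directions are those of the libraries labelled CSE-KO relative to those labelled WT.

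Cth, which encodes CSE, the enzyme that releases cysteine from cystathionine and can form hydrogen sulfide, was higher in the libraries labelled CSE-KO. Its normalized counts were 29, 27 and 26 in WT 1 to 3 and 49, 43 and 63 in CSE-KO 1 to 3, or 27.3 ± 1.53 against 51.7 ± 10.3. The log2 fold change was 0.89 (SE 0.18, adjusted p = 0.00079), which goes against the label. Cth (ENSMUSG00000028179) lies on chromosome 3 from 157894248 to 157925077, on the minus strand. The deleted exons are not given in the sources used here, and a value summed over the whole gene includes exons outside a deletion, so these values do not check whether part of Cth was removed. Groups are therefore named by their labels throughout.

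The libraries labelled CSE-KO showed a broad change in which amino acid stress, antioxidant and p53 target genes and transcripts of macrophages rose, and mitotic, sterol synthesis and endothelial genes fell. The calls of these gene lists were lost when the correlation between genes was estimated (adjusted p between 0.407 and 0.550). The cystine carrier Slc7a11 rose 5.58-fold (from 654 ± 11.5 to 3653 ± 90.1), Chac1, a glutathione-degrading enzyme, rose 10.1-fold (from 64.3 ± 11.6 to 647 ± 45.1), and the cationic amino acid carrier Slc7a3 rose 121-fold (from 6.00 ± 2.00 to 760 ± 21.5). The proliferation marker Mki67 was at 3155, 3086 and 3077 in WT 1 to 3 and at 1057, 635 and 614 in CSE-KO 1 to 3. The Notch ligand Dll4 fell from 856 ± 24.8 to 64.0 ± 47.3. The endothelial cadherin gene Cdh5 moved only from 2829 ± 17.8 to 2673 ± 6.43 (log2 fold change −0.08, adjusted p = 0.0012). A change this small depends on the scaling, since the median log2 fold change of all tested genes was 0.001 here and 0.077 with equal totals. After the correction for reads lost at shared start positions, the log2 fold change of Cdh5 was −0.15.

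In number, 10639 of 13750 tested genes (77.4%) changed, of which 5270 rose and 5369 fell. At least a 2-fold change was seen in 1365 of the genes that rose and 1694 of those that fell, and 2228 changed by under 1.2-fold. These 2-fold counts depended on the filter, with 718 and 1254 at a minimum value of 50 and 2217 and 2134 with no filter, where more rose than fell. The changed genes included 9892 protein-coding genes. The groups did not overlap in 11053 tested genes (80.4%), where chance gives 10%. A test against a fold of 1.2 in either direction called 6711 genes, the only setting that moved the count of changed genes by over 1.5 times. The first principal component held 91.6% of the variance and separated the groups. On the second, CSE-KO 1 lay at −20.0, CSE-KO 2 at −0.59 and CSE-KO 3 at 17.5. CSE-KO 1 was the nearest of the 3 CSE-KO libraries to WT in 6175 changed genes (58.0%, against 33.3% by chance), and its changes had a slope of 0.853 against the mean of the other 2 CSE-KO libraries. The labels do not say that the replicates were separate animals or cultures, and the WT libraries differed from each other by no more than counting noise. So did CSE-KO 2 and 3 over all genes (index 0.862), though not in genes under 0.01 per exonic base (1.11). With WT 1 to 3 counted as 1 sample, an alternative added after the data were seen, the log2 fold change of Cth was 0.89. Averaging the WT libraries hardly alters a difference of group means, so this value is no check of the change. The spread in that fit came only from the CSE-KO libraries. No fit counted both WT 1 to 3 and CSE-KO 2 and 3 as 1 sample.

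**Figure D1:**
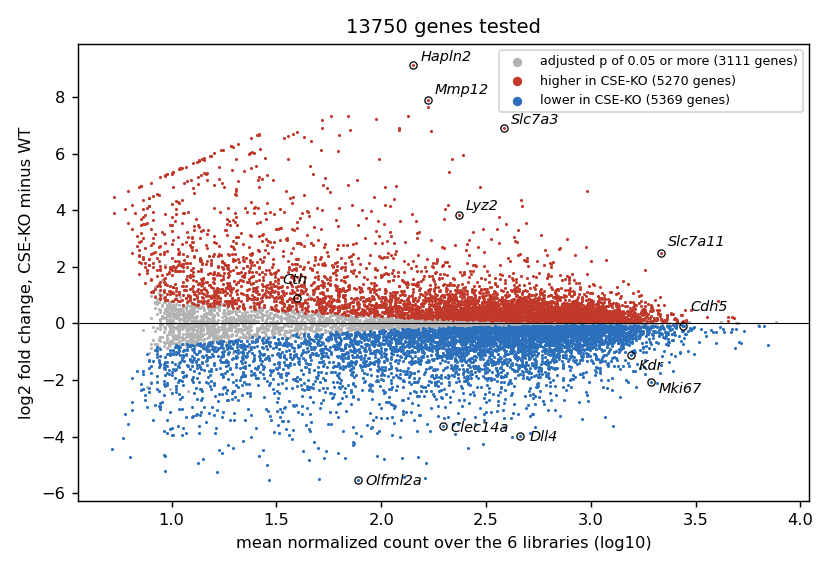
Each point is 1 of the 13750 tested genes, with the mean normalized count over the 6 libraries on the horizontal axis (log10) and the log2 fold change of CSE-KO minus WT on the vertical axis. Red points are the 5270 genes that rose, blue points the 5369 that fell and grey points the others, and points at the upper left edge are genes near 0 in WT, whose height depends on the 0.5 added to each value.

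The 12 largest rises were in genes that were near 0 in WT. Hapln2, a hyaluronan link protein of the nervous system (ENSMUSG00000004894, chromosome 3, 88021750 to 88027583), was listed at 0 in all WT libraries and at 251, 288 and 315 in CSE-KO 1 to 3. Mmp12, macrophage elastase, was at 3, 0 and 1 in WT and at 305, 364 and 325 in CSE-KO. Mmp8, neutrophil collagenase, was at 1, 0 and 2 against 133, 146 and 145. The chemokine genes Cxcl5 and Ccl6 stood at 1.00 ± 1.00 and 1.67 ± 0.58 in WT and at 188 ± 28.9 and 241 ± 19.7 in CSE-KO. Lilr4b, a leukocyte immunoglobulin-like receptor, went from 0, 1 and 0 to 121, 116 and 109. The secreted factors Wnt11 (0, 2 and 3 against 320, 341 and 335), Adm2 (3, 2 and 0 against 249, 272 and 275) and Nppb (6, 0 and 2 against 234, 244 and 246) rose as well. Xirp2, which binds actin in striated muscle (0, 0 and 1 against 93, 114 and 106), and the transcription factor Mef2b (2, 0 and 0 against 100, 99 and 112) completed the set with Slc7a3 (log2 fold change 6.92, SE 0.20, adjusted p = 2.0e-09; chromosome X, 101079210 to 101086020). The adjusted p of the 12 genes was at most 0.0022. The list of macrophage markers rose in the same libraries (adjusted p = 0.407 with an estimated correlation), with Mpeg1, a pore-forming protein of phagocytes, at 7.33 ± 1.53 in WT and 229 ± 54.5 in CSE-KO.

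The 12 largest falls included genes of endothelial surfaces and signalling. Clec1a, a C-type lectin of endothelial and dendritic cells, was at 297, 327 and 301 in WT 1 to 3 and at 43, 6 and 3 in CSE-KO 1 to 3 (adjusted p = 0.012). Cd300lg, a capillary receptor, was at 97, 117 and 94 against 8, 2 and 2. The receptor tyrosine kinase Ephb1 was at 284, 303 and 263 against 30, 11 and 3 (adjusted p = 0.0064), and the protein kinase C gene Prkcq at 247, 238 and 228 against 30, 6 and 3 (adjusted p = 0.0067). Tril, a co-receptor of Toll-like receptor signalling, fell by 4.81 on the log2 scale (log2 fold change −5.47 without CSE-KO 1), from 198 ± 1.53 to 8.33 ± 7.51. The others were Dipk2b (83, 120 and 92 against 5, 3 and 0), Olfml2a (148, 154 and 149 against 10, 6 and 0), Fam20a (255, 240 and 245 against 29, 2 and 2), Chodl, Mmp15, Creg2 and Dchs2. The log2 fold change of Olfml2a was −5.54 with all libraries, −6.39 without CSE-KO 1 and −4.19 without CSE-KO 3. Among the CSE-KO libraries, CSE-KO 1 was the highest in all 12 of these falls and the lowest in 10 of the 12 largest rises. Chodl (320, 297 and 306 against 35, 6 and 1) lost its call without CSE-KO 2 (adjusted p = 0.056, against 0.016 with all libraries). With WT counted as 1 sample, Olfml2a, Chodl, Fam20a, Clec1a, Prkcq and Ephb1 lost theirs (adjusted p between 0.077 and 0.149).

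Of the 37 lists tested, 15 passed, 9 upward and 6 downward. None passed in camera when the correlation between genes was estimated for each list, where 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.407, and 32 passed by fry. Where no separate count is given, the count adjusted over the list alone was the same. ATF4 and integrated stress response genes, which cells induce when amino acids run short or unfolded protein builds up, rose in 36 of 37 tested members and fell in 0. Their median log2 fold change was 0.95 (camera adjusted p = 1.6e-12, and adjusted p = 0.407 with an estimated correlation). Asparagine synthetase Asns rose from 426 ± 15.6 to 1232 ± 4.93, the transcription factor Atf5 from 371 ± 5.13 to 1261 ± 15.6, the mitochondrial carboxykinase Pck2 from 580 ± 13.2 to 1497 ± 55.8 and the secreted glycoprotein Stc2 from 7.33 ± 2.08 to 426 ± 12.3. Atf4 itself rose by a log2 fold change of 0.48, and Ddit3, the stress factor CHOP, by 2.67. In 30 of the 37 members CSE-KO 1 was the lowest CSE-KO library. Cth is itself a member of this list, and 6 of the 37 belong to another list.

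NRF2 targets, the antioxidant programme, rose in 20 of 27 members and fell in 5 (21 and 5 adjusted over the list alone), with a median of 0.54 (adjusted p = 0.00072, and 0.407 with an estimated correlation). Osgin1, an oxidative stress response gene, rose 7.10-fold from 89.3 ± 7.51 to 637 ± 37.8. Thioredoxin reductase Txnrd1 rose from 1458 ± 20.8 to 2569 ± 37.4 and sulfiredoxin Srxn1 from 912 ± 6.66 to 1526 ± 19.9. Cystine import and glutathione genes rose in 14 of 23 members and fell in 7 (15 and 7 adjusted over the list alone), and the list did not pass (median 0.33, adjusted p = 0.063). It passed with no filter on low values (adjusted p = 0.049). Within it, Slc7a11 (chromosome 3, 49892526 to 50443614) had the smallest adjusted p of all tested genes, 5.3e-13, with a log2 fold change of 2.48. Its partner chain Slc3a2 rose from 644 ± 15.9 to 1250 ± 31.2, the neutral amino acid carrier Slc1a4 from 192 ± 9.02 to 1044 ± 53.6, and Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, from 728 ± 20.7 to 1428 ± 49.4. The glutathione peroxidase Gpx3 fell from 749 ± 25.1 to 367 ± 45.6.

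Transsulfuration, methionine and hydrogen sulfide genes rose in 4 and fell in 11 of 22 members, and the list did not pass (median −0.15, adjusted p = 0.244). The aspartate aminotransferase Got1 rose from 393 ± 2.31 to 727 ± 5.86. Cbs, which acts just before CSE in the pathway, fell by 1.59 on the log2 scale, and Mpst, another enzyme of hydrogen sulfide formation, fell from 227 ± 10.4 to 163 ± 7.37. Acetyl-CoA supply genes rose in 6 and fell in 14 of 23 members (median −0.23, adjusted p = 0.140). The pyruvate dehydrogenase kinases moved apart, with Pdk4 rising from 166 ± 19.9 to 790 ± 4.93 and Pdk1 falling from 969 ± 50.4 to 443 ± 33.0. ATP citrate lyase, Acly, fell by 0.34 on the log2 scale, from 1813 ± 22.9 to 1436 ± 27.4. Histone acetyltransferase genes rose in 7 and fell in 7 of 16 members, with a median of 0.01 above 0 and a camera test directed downward (adjusted p = 0.933). The cofactor Trrap fell from 2349 ± 34.2 to 1498 ± 65.9 and Ncoa1 rose by 0.88 on the log2 scale. Histone deacetylases and sirtuins rose in 4 and fell in 9 of 17 members (median −0.12, adjusted p = 0.409), with Hdac9 falling from 86.7 ± 2.52 to 21.3 ± 1.53.

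Cell cycle genes fell together. Of the G2/M and mitosis genes, all 32 fell, with a median of −1.79 (adjusted p = 6.1e-08, and adjusted p = 0.550 with an estimated correlation). The kinetochore gene Cenpf was at 1616, 1666 and 1622 in WT and at 320, 117 and 106 in CSE-KO 1 to 3. The spindle checkpoint kinase Bub1 fell from 674 ± 15.9 to 213 ± 25.6, and the midzone protein Prc1 from 960 ± 16.1 to 533 ± 21.1. In each of the 32, CSE-KO 1 was the highest CSE-KO library. G1/S and DNA replication genes rose in 1 and fell in 27 of 30 members (2 and 27 adjusted over the list alone), with a median of −0.51 (adjusted p = 1.4e-05, and 0.407 with an estimated correlation). The DNA polymerase Pole fell from 1029 ± 2.52 to 462 ± 36.4 and the chromatin assembly factor Chaf1a from 684 ± 17.1 to 339 ± 23.8. Genes activated by p53 rose in 19 and fell in 4 of 23 members, with a median of 0.58 (adjusted p = 0.00033, and 0.407 with an estimated correlation). The stress cytokine Gdf15 rose 11.5-fold from 62.7 ± 6.66 to 726 ± 26.1, the cell cycle inhibitor Cdkn1a from 816 ± 11.1 to 1394 ± 21.3, Mdm2, which degrades p53, from 862 ± 6.25 to 1551 ± 30.9, and the cell death gene Pmaip1 from 77.3 ± 13.8 to 907 ± 17.5.

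Lipid synthesis genes fell. Cholesterol synthesis genes fell in 21 of 23 members and rose in 1 (22 and 1 adjusted over the list alone), with a median of −0.79 (adjusted p = 2.7e-05, and 0.407 with an estimated correlation). The sterol-sensing transcription factor Srebf2 fell from 1760 ± 18.9 to 1169 ± 49.3 and Hmgcs1, an early enzyme of the pathway, from 817 ± 12.9 to 489 ± 29.0. Fatty acid synthesis genes fell in 13 of 16 members and rose in 2, with a median of −0.69 (adjusted p = 0.0030, and 0.407 with an estimated correlation). The desaturase Scd1 fell from 631 ± 18.5 to 208 ± 26.1 and the acetyl-CoA carboxylase Acaca by 1.13 on the log2 scale. The value of CSE-KO 1 was the highest of the CSE-KO libraries in 16 of the 23 cholesterol genes and 9 of the 16 fatty acid genes.

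Endothelial identity genes fell in 27 of 32 members and rose in 1 (27 and 3 adjusted over the list alone), with a median of −0.83 (adjusted p = 1.4e-05, and 0.407 with an estimated correlation). After the correction for reads lost at shared start positions, the list median was −0.97. Endothelial nitric oxide synthase, Nos3, fell from 574 ± 16.6 to 216 ± 12.3, the angiopoietin receptor Tek by 1.57 on the log2 scale and the VEGF receptor genes Kdr from 2143 ± 26.2 to 980 ± 76.6 and Flt1 from 785 ± 48.5 to 208 ± 32.7. Clec14a, an endothelial surface lectin, went from 362 ± 12.5 to 31.3 ± 17.1 (log2 fold change −3.63, adjusted p = 0.00038). The members did not move alike. The sialomucin gene Emcn was at 1386 ± 26.5 in WT and 1404 ± 8.72 in CSE-KO and did not pass, nor did the transcription factor gene Gata2 (adjusted p = 0.052), and Ets1 rose by 0.25. In 23 of the 32 members CSE-KO 1 was the highest CSE-KO library. The list of macrophage transcripts rose in the same libraries (adjusted p = 0.407 with an estimated correlation), with Lyz2 going from 31.0 ± 7.21 to 438 ± 29.0.

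Transcripts of lymphatic endothelium, which were abundant in WT, fell in 9 of 11 members and rose in 1, with a median of −1.09 (adjusted p = 0.010, and 0.557 with an estimated correlation). Prox1, the factor that sets lymphatic fate, fell from 2788 ± 16.1 to 832 ± 219, Lyve1 from 2066 ± 24.3 to 1063 ± 232, Flt4, the VEGF-C receptor, from 4238 ± 72.8 to 2004 ± 304, and Reln from 2372 ± 86.2 to 397 ± 86.9. CSE-KO 1 was the highest CSE-KO library in 9 of the 11. Macrophage transcripts rose as a list in the same libraries (adjusted p = 0.407 with an estimated correlation). The lists of other vascular beds did not pass. General capillary markers rose in 3 and fell in 5 of 9 members (median −0.12, adjusted p = 0.604), with Gpihbp1, which anchors lipoprotein lipase, falling from 62.3 ± 7.23 to 5.33 ± 1.53. Aerocyte markers rose in 5 and fell in 3 of 11 (median 0.00, adjusted p = 0.692), with Kitl rising from 64.0 ± 7.81 to 449 ± 23.6. Arterial markers rose in 5 and fell in 7 of 15 (median −0.17, adjusted p = 0.692), and venous markers rose in 3 and fell in 4 of 10 (4 and 6 adjusted over the list alone, median −0.15, adjusted p = 0.604), with the venous factor Nr2f2 falling from 1320 ± 10.7 to 595 ± 78.5.

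Angiogenesis and tip cell genes rose in 9 and fell in 15 of 28 members and did not pass (median −0.29, adjusted p = 0.557), although fry was directed upward. The growth factor genes Pgf and Vegfa rose from 242 ± 6.08 to 1042 ± 20.8 and from 259 ± 16.3 to 1027 ± 58.8, and the co-receptor Nrp1 from 71.3 ± 6.51 to 437 ± 14.7, whereas Dll4, in this list and the arterial one, fell by 3.98 on the log2 scale (adjusted p = 0.0028). Shear and KLF response genes rose in 7 and fell in 5 of 14 (median 0.10, adjusted p = 0.494), with thrombomodulin, Thbd, rising from 773 ± 14.2 to 1886 ± 29.8. TGF-beta and BMP response genes rose in 9 and fell in 12 of 23 (9 and 13 adjusted over the list alone, median −0.14, adjusted p = 0.657). Mesenchymal transition and matrix genes rose in 10 and fell in 10 of 26, with a median just under 0, a mean of 0.16 and a camera test directed upward (adjusted p = 0.867). The transcription factor Zeb2 rose from 230 ± 15.9 to 964 ± 49.0. Hypoxia and glycolysis genes rose in 10 and fell in 13 of 32 (median −0.04, adjusted p = 0.616). Respiratory chain genes encoded in the nucleus rose in 7 and fell in 6 of 34 (7 and 4 adjusted over the list alone, median 0.04, adjusted p = 0.561). The respiratory chain counts depended on the scaling, with 16 rising and 4 falling under upper-quartile scaling, where the list did not pass either (camera adjusted p = 0.291).

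Inflammatory and interferon genes rose. Endothelial adhesion and inflammation genes rose in 19 and fell in 4 of 27 members, with a median of 0.56 (adjusted p = 0.0029, and 0.407 with an estimated correlation). Cyclooxygenase 2, Ptgs2, rose from 774 ± 18.5 to 2860 ± 32.5, the NF-kB inhibitor Tnfaip3 from 435 ± 14.8 to 1475 ± 47.6 and the neutrophil chemokine Cxcl2 from 22.7 ± 2.08 to 380 ± 21.4, and fractalkine, Cx3cl1, fell from 411 ± 30.2 to 106 ± 4.36. Interferon-stimulated genes rose in 24 and fell in 0 of 29 members, with a median of 0.47 (adjusted p = 0.0010, and 0.716 with an estimated correlation). The RNA sensor Ddx58 rose by 0.34 and Isg15 by 0.45 on the log2 scale. Of the CSE-KO libraries, CSE-KO 1 was the lowest in 24 of these 29 genes and in 17 of the 27 inflammation genes, and the macrophage marker list rose in the same libraries (adjusted p = 0.407 with an estimated correlation). Antigen presentation genes rose in 8 and fell in 5 of 14 (median 0.16, adjusted p = 0.604).

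Markers of other cell types moved with the groups. Macrophage and monocyte genes rose in 17 and fell in 1 of 19 members, with a median of 5.40, or 3.13 when the 11 members with a group mean under 3 were set to their lower bound (adjusted p = 1.4e-05, and 0.407 with an estimated correlation). Adgre1, which encodes F4/80, was at 0 in all WT libraries and at 36, 62 and 56 in CSE-KO 1 to 3, the scavenger receptor Marco at 0 against 41, 40 and 62, and the leukocyte gene Ptprc at 0 against 18, 25 and 23. The complement gene C1qb was at 2, 0 and 2 against 90, 109 and 108, and the cathepsin Ctss at 1.33 ± 0.58 against 123 ± 20.1. Cd14 fell from 779 ± 7.51 to 239 ± 67.1, and Mrc1, at 97.0 ± 16.1 and 90.7 ± 14.8, did not pass. Mesothelial genes rose in 6 and fell in 1 of 7, with a median of 3.70, or 3.23 with members near 0 at their bound (adjusted p = 0.040, and 0.407 with an estimated correlation). The keratin gene Krt19 rose from 185 ± 3.06 to 550 ± 22.2 and Aldh1a2, a retinoic acid synthesis enzyme, from 5.00 ± 2.00 to 83.0 ± 6.56. Mesothelin, Msln, was at 2.67 ± 1.53 in WT and 54.3 ± 4.93 in CSE-KO. The mesothelial call was lost under upper-quartile scaling, equal totals, quantile normalization and a minimum value of 50 (adjusted p between 0.063 and 0.175).

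The other marker lists did not pass. Of 22 lymphocyte and granulocyte genes listed, only 6 were present in the data and 3 were tested. These 3 rose (median 2.88, or 2.43 at the bound, adjusted p = 0.054), with the chemokine Ccl5 going from 31.0 ± 6.56 to 229 ± 28.0. Of 14 alveolar type 2 genes listed, only 5 were present in the data. The 3 tested fell (median −1.16, adjusted p = 0.054), among them Abca3 from 1581 ± 18.9 to 712 ± 73.4. Both of these lists passed under some other settings of the camera test (adjusted p between 0.037 and 0.048). Alveolar type 1 and airway epithelial genes rose in 1 and fell in 3 of 7 (median −0.48, adjusted p = 0.541), with fry directed upward. Fibroblast genes rose in 4 and fell in 4 of 11 (median −0.13, adjusted p = 0.964), again with fry directed upward, and Dcn went from 74.7 ± 1.53 to 319 ± 33.6 while Itga8 went from 305 ± 27.3 to 38.7 ± 12.5. Mural cell genes rose in 7 and fell in 5 of 14 (median 0.43, adjusted p = 0.541), with desmin, Des, rising by 3.62 on the log2 scale and the potassium channel Kcnj8 falling from 182 ± 6.08 to 13.3 ± 5.86. Only 2 erythroid genes were tested, too few for the set test, of which 1 rose and 1 fell. Sex-linked genes rose in 2 and fell in 1 of 4 (median 0.22, adjusted p = 0.692). Xist was at 0, 1 and 0 in WT and 2, 3 and 1 in CSE-KO and was not tested, and the Y-linked Ddx3y was at 825 ± 31.2 and 1194 ± 31.8.

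Of the sample quality lists, immediate early and dissociation genes rose in 16 and fell in 7 of 25 members, with a median of 0.58 (adjusted p = 0.043, and 0.427 with an estimated correlation). The heat shock gene Hspa1a rose 17.8-fold from 49.3 ± 5.03 to 886 ± 24.5 and the chaperone Dnajb1 from 560 ± 10.4 to 1402 ± 41.4. The immediate early genes Fos and Fosb fell by 1.28 and by 2.17 on the log2 scale, while Atf3 rose by 1.43. The call of this list was lost without WT 2, WT 3 or CSE-KO 1, with the replicate number as a block and under 4 other scalings or filters (adjusted p between 0.051 and 0.076). Cytosolic ribosomal protein genes rose in 19 and fell in 1 of 34 (18 and 1 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.0048, and 0.649 with an estimated correlation). These counts depended on the scaling, with 27 rising and 0 falling under upper-quartile scaling. Rpl10a rose by 0.64 and Rps19 by 0.33 on the log2 scale. Mitochondrially encoded genes were not in the table.

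**Figure D2:**
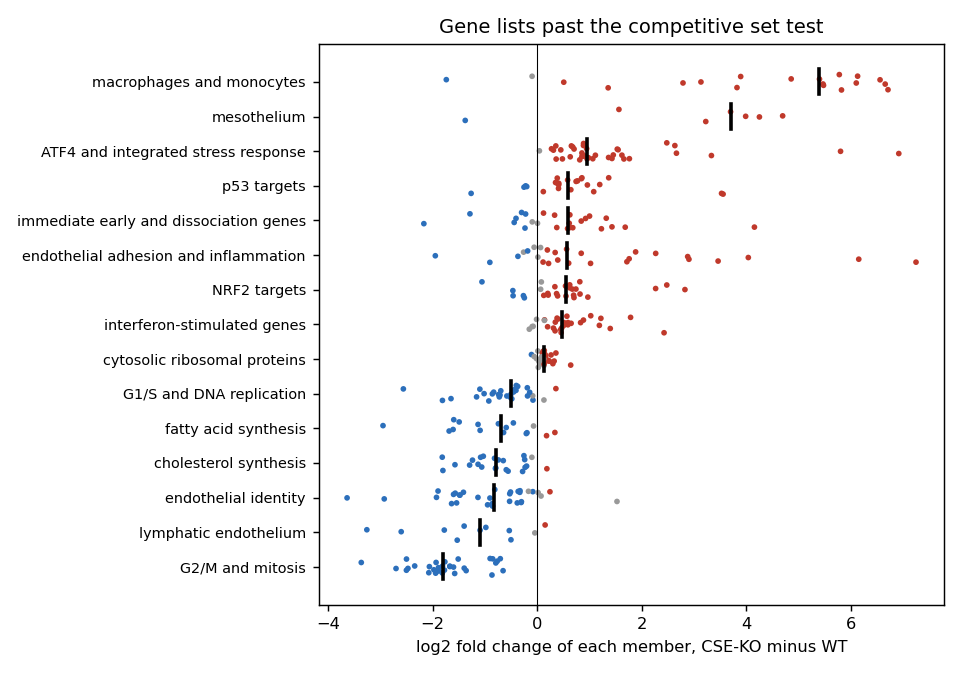
Each point is a tested member of 1 of the 15 lists that passed the set test, at its log2 fold change of CSE-KO minus WT, and black bars are medians. Red members rose, blue members fell and grey members did not pass, so that the mitosis genes lie left of 0 and all but 1 of the 37 ATF4 genes are red.

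**Figure D3:**
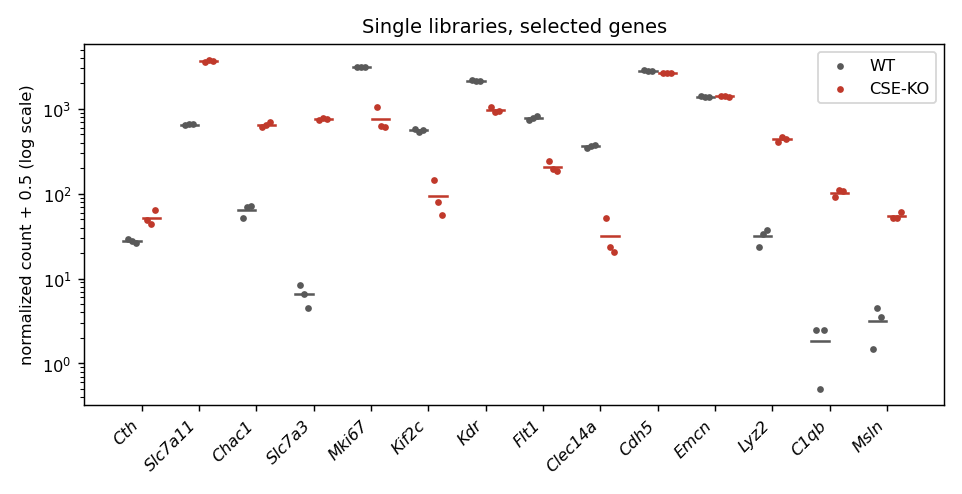
Normalized counts plus 0.5 of selected genes are drawn on a log axis, 1 point per library with a bar at the group mean, for WT in grey and CSE-KO in red. Slc7a11 and Lyz2 stand higher and Mki67, Kdr and Clec14a lower in CSE-KO, Cdh5 and Emcn lie close together, and Cth lies higher in the 3 libraries labelled CSE-KO.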

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

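The added scalings and filters (equal totals, quantile normalization, a minimum of 50, the start-position correction) and the fits with CSE-KO 2 and 3 or WT 1 to 3 counted as 1 sample were chosen only after the data were seen. The test against a fold of 1.2 by limma treat called 6711 genes. Of the lists, 0 passed with an estimated correlation and 32 by fry, against 15 by camera with the fixed correlation. Camera with an estimated correlation also tests on far fewer degrees of freedom, so the lost calls cannot be put down to correlation between members alone. The adjusted p rose also for each list with a negative estimated correlation, such as lymphocytes and granulocytes (correlation −0.21, camera adjusted p from 0.054 to 0.407). How much each difference contributed was not tested. With each library left out in turn, the count of changed genes lay between 10137 and 10636, of genes that rose between 4999 and 5231, of genes that fell between 5101 and 5405, of lists past the threshold between 14 and 16, and the log2 fold change of Cth between 0.74 and 1.01. With the replicate number as a block, 10440 genes changed and 14 lists passed. The numbers were not treated as pairs, because the labels do not say that equal numbers belong together. The counts of the fit with WT counted as 1 sample are not compared here. The settings that moved a count by over 1.5 times were the test against a fold of 1.2, the estimated correlation and fry. All others left each of the 3 counts and the lists within 1.5 times their value. Among those others, the lowest count was 9123 genes at a minimum of 50 and the highest 11859 with no filter. The fit with WT counted as 1 sample assumes that the lone sample varies like the others. Cth itself was not tested under the minimum of 50. Under quantile normalization 14 calls took the opposite direction. The share of changed genes that rose was 49.5% and ranged from 47.4% to 55.9% over the settings. Of 166 named genes tested, 14 changed call under at least 1 setting and 0 reversed, and 0 lists reversed. Besides the mesothelial and immediate early lists, the 13 other lists that passed kept their call under all settings run on lists but the estimated correlation. The planned DESeq2, limma-voom and edgeR fits need counts and were not run, and glmTreat was replaced by limma treat. Depth limits the genes near 0, where a whole number of reads decides the value. In simulation 46% of true changes of 1.2-fold were called, but only 200 of 13750 genes were changed there. That share therefore does not carry over to the data.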

Other observations

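The tests of foreign cells, of the endothelial share, of RNA shared with WT, of scaling and of reads kept per start position were chosen only after the results were seen, as were the 21 gene families, the intervals of the density ratio and its comparison with the class from 0.03 to 0.1 per exonic base. Of the 21 families, 8 passed in camera and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05 and the smallest adjusted p was 0.157. Members were taken by symbol, and genes that share only a prefix were left out; with these included, kinesins passed as well (adjusted p = 0.045, against 0.066). Protocadherins, cell adhesion proteins known from neurons, fell in 38 of 43 tested members and rose in 3 (median −1.49, camera adjusted p = 7.3e-06, and adjusted p = 0.293 with an estimated correlation). Pcdh12, an endothelial member, went from 991 ± 36.9 to 88.7 ± 56.7, and clustered members such as Pcdhb22 from 304 ± 0.58 to 80.3 ± 16.3, while Pcdh17 rose from 113 ± 5.29 to 385 ± 60.6. Aminoacyl-tRNA synthetases rose in 18 of 20 members and fell in 2 (median 0.59, adjusted p = 7.6e-05, and 0.293 with an estimated correlation), with Aars going from 1139 ± 13.7 to 2250 ± 57.5 and Cars from 723 ± 26.1 to 1542 ± 39.4. Several of these are also in the ATF4 list. Proteasome subunits, activators and assembly factors rose in 36 of 48 and fell in 5 (median 0.26, adjusted p = 0.00024, and 0.293 with an estimated correlation), with Psmd8 going from 663 ± 14.3 to 981 ± 24.4. Heat shock and DNAJ chaperone genes rose in 38 of 62 and fell in 15 (adjusted p = 0.0064, and 0.293 with an estimated correlation). Members such as Hspa1a, Hspa1b and Dnajb1 are also in the immediate early and dissociation list. That sample quality list rose in 16 and fell in 7 of 25 (adjusted p = 0.427 with an estimated correlation). The mitochondrial ribosomal protein genes rose in 39 of 76 and fell in 12 (adjusted p = 0.024, and 0.293 with an estimated correlation), and zinc finger genes named Zfp rose in 184 of 336 and fell in 65 (adjusted p = 0.00024, and 0.157 with an estimated correlation).

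Chemokine genes rose in 15 of 18 members and fell in 2 (median 1.79, adjusted p = 0.00072, and adjusted p = 0.182 with an estimated correlation). Cxcl12 rose from 835 ± 20.1 to 2186 ± 101 and Cxcl10 from 57.0 ± 8.19 to 275 ± 14.4. Macrophage markers rose in the same libraries, in 17 of 19 members (adjusted p = 0.407 with an estimated correlation). Semaphorins and plexins, guidance cues and their receptors, fell in 18 of 25 and rose in 3 (median −1.10, adjusted p = 0.0040, and 0.293 with an estimated correlation), with Sema6d falling from 489 ± 34.4 to 148 ± 3.79 and Sema3c rising from 6.67 ± 2.08 to 119 ± 18.2. Genes of the Notch pathway fell in 9 of 13 and rose in 3, and the family did not pass (median −0.72, adjusted p = 0.133). Besides Dll4, the targets Hey1 (331 ± 36.4 to 68.0 ± 26.3) and Nrarp (log2 fold change −2.55) and the receptor Notch4 (2415 ± 57.5 to 759 ± 109) fell, while Notch2 rose from 884 ± 36.1 to 1230 ± 25.6. Each of those that fell was highest in CSE-KO 1 among the CSE-KO libraries. Serpins rose in 11 of 18 and fell in 5 and did not pass (adjusted p = 0.133), with Serpinb2 rising from 19.7 ± 2.08 to 571 ± 50.3.

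The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 10639 changed genes, the highest of the other 9 gave 0, and 1 of the 10 splits, the real one, gave as many.

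Macrophage transcripts were higher and the endothelial list lower in the libraries labelled CSE-KO. A smaller share of endothelial cells as the only cause is argued against, because 9 of the 30 endothelial members with a WT mean of at least 300 lay more than 2 SE above −0.49, the list's median after the start-position correction multiplied by 0.5, among them Cdh5 and Emcn. Macrophages in the CSE-KO cultures remain a candidate explanation of the first part, since the 11 macrophage members with a WT mean under 3 (totals 513, 666 and 640 in CSE-KO 1 to 3) differed in their proportions between these libraries by no more than counting noise, with a heterogeneity of 0.725 per degree of freedom, which 2.8% of random sets of other genes risen from near 0 reached, around a median of 1.3. The 6 mesothelial members that rose, not limited to a WT mean under 3, differed by more than counting noise. Their heterogeneity was 1.91 per degree of freedom (chi-square test, p = 0.039). An effect of the genotype on the macrophage genes remains open and was not tested apart from the groups. No sort or gate is given in the sources used here.

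CSE-KO 1 lay between WT and the other CSE-KO libraries. A scaling error is argued against, because 1 factor would shift all genes alike, whereas the median log2 ratio of CSE-KO 1 to the mean of CSE-KO 2 and 3 was 0.08 in the genes that fell and −0.04 in those that rose, a difference of 0.127 (95% interval 0.121 to 0.132). A share of WT-like RNA in CSE-KO 1, or of cells that kept the WT state, may account for part of the pattern. Such a share came to 10.6% from 11 genes gained (95% interval 5.35 to 16.8) and to 12.2% from 12 genes lost (10.7 to 14.1). Both sets were chosen by a large difference between WT and the mean of CSE-KO 2 and 3. CSE-KO 1 had no part in that choice and may lie nearer to WT for that reason alone. No other library was held out in the same way. The mitosis list gave 15.8% and the macrophage totals gave 21.6%. No interval was computed for either, so they cannot be ranked against the intervals above. The shares differed between 20 gene lists (medians from 4.93% to 18.9%, permutation test of the Kruskal-Wallis statistic, p = 0.0001, the smallest it can give). CSE-KO 2 and 3 differed between these lists too (permutation test, p = 0.0001), so such a share as the only cause cannot be told apart from other variation between libraries, and a weaker response of the same cells in this culture was not tested.

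Fold changes were smaller in genes with more reads per exonic base. Counting noise in sparse genes as the cause is argued against among the 4358 genes with a mean of at least 500, where the median absolute change of the sparsest class was 2.0 times that of the densest (interval 1.10 to 3.69, with 20 genes in the sparsest class) and that of the class from 0.03 to 0.1 was 2.02 times (1.59 to 2.58). Removal of reads that share a start position may account for part of it. The spread between WT libraries at 0.2 to 0.4 per exonic base had an index of 0.549, under the 1 of counting noise. Under 0.01 per exonic base the index was 0.966. After a correction for such removal the ratio of the sparsest to the densest class was 1.45, and no interval was computed for it. The correction assumes the removal and enlarges changes more in denser genes. A lower ratio was therefore built in, and it cannot decide whether reads were removed. A difference in regulation between abundant and sparse genes was not tested.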
